A study of Homo sapiens with 8 samples.

How the data were processed

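RNA sequencing of total RNA was deposited for 2 breast cancer cell lines, MDA-MB-468 and MCF7. Each line was represented by 4 groups with 1 sample each: a non-target control (NTC), a DVL3 knockdown named shB, an empty vector (EV) and an overexpression of wild-type DVL3 (DVL3-WT). Per the labels' protocols, the cells were grown in RPMI medium with fetal bovine serum, RNA was isolated with a column kit for total RNA, and strand-specific libraries were made with the NEBNext Ultra II Directional kit. The aligner, the annotation and the genome build are not given in the sources used here, so no coordinates are printed.

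The deposited table of all genes holds linear RPKM values (reads per kilobase of gene, relative to all mapped reads), 1 column per group and 27715 rows. The authors also deposited 4 tables of their own comparisons, with an RPKM value for both groups, a fold change as a linear ratio, 2 t values, which are scores without a fixed range, and 2 p-values per gene. The deposited tables hold only rows with a first p-value of at most 0.05 and a fold of at least 2 in either direction, which was checked on the values. In all rows the first p-value was that of a t statistic with 4 degrees of freedom, so each RPKM column was taken as the authors' mean over several libraries, inferred as 3. The libraries behind a column were not used here, so values are printed as the authors' means without SD or n. The method behind the second p-value is not named in the deposited tables; it fell in step with the second t value and had plateaus, as a p-value adjusted for many tests has. In the deposited fold columns a value of 0 was replaced by a floor of about 0.00033 RPKM. In the table of the MCF7 overexpression, the first fold column was the ratio of DVL3-WT to NTC in 89 of 89 rows checked (within 0.02 on the log2 scale), and the second fold column was used for DVL3-WT against EV.

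Rows named as calendar dates (28 rows, damaged gene symbols), 25 identical repeats of a row and 17 names with several different rows (34 rows) were left out, which left 27628 genes. The number of RPKM columns without a group was 0. The read totals behind the RPKM values are unknown, so no counting interval is given. A large part of the summed RPKM lay in structural RNAs: RNA45S5, the precursor of ribosomal RNA, took between 12.2% and 45.8% of it. Since RPKM is relative to all mapped reads, this moves all other genes of a column together. For this reason each comparison is given as deposited and after rescaling by the median of ratios, over the 2856 genes with at least 1 RPKM in each column.

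Log2 ratios were taken on log2(RPKM + 1), which understates the change of low genes. With 1 column per group no test between groups of 1 line was possible, and genes were counted by a fixed size rule: a log2 ratio of at least 1 in either direction. Genes said to be at least 2-fold higher, lower or apart are those past this rule, on RPKM + 1. A low gene whose plain ratio is over 2-fold can fall short of it. Knockdown was compared with NTC and overexpression with EV, and EV was compared with NTC as a control comparison. For 29 gene lists, the median log2 ratio of the members with a mean of at least 1 RPKM over the 8 columns was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list needed 5 such members, which 25 lists had. It was said to stand apart when its median lay under the 2.5th or over the 97.5th percentile; this describes these columns and is not a test between conditions. An effect common to both lines was tested with limma (version 3.58.1, R 4.3.3, empirical Bayes with a trend) on log2(RPKM + 1) of the 8683 genes with a mean of at least 1 RPKM, with terms for cell line and arm and Benjamini-Hochberg adjustment at 0.05. The lines are the replicates there, 2 per arm. Chance counts of genes past the size rule in 2 comparisons were taken over genes that could pass it in both, a universe set after the data had been seen. Correlations across genes are described without p, since genes are not independent replicates. The design had assumed values of single libraries; the columns turned out to be means, and the tests were kept as fixed. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

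The grouping, the tests, the gene lists and the alternatives were fixed before the data were examined, apart from alternatives named as added later. The rule for named genes takes, per comparison, DVL1, DVL2 and DVL3, the 8 genes with the highest and the 8 with the lowest log2 ratio among genes of at least 5 RPKM in the higher column (leaving out LOC, LINC and dotted clone names), up to 4 members of each list that stands apart, up to 5 reciprocal genes per line, and for the common effect the genes past the threshold or else 5 per direction with the largest smaller log2 ratio of the 2 lines. Alternatives were pseudocounts of 0.1 and 0.5, minimum levels of 5 and 10 RPKM, rescaling, quantile normalization, means in place of medians of lists, other settings of limma, leaving out each column from the limma fit, and a threshold of 0.01 for the authors' tables.

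The steps were tested on simulated data. With a residual SD of 0.15 on the log2 scale, the limma step found 100% of genes changed 2-fold, 4-fold or 64-fold in both the knockdown and the overexpression arm, among 8683 genes of which 200 were changed. With the residual SDs of the real fit (median 0.874) it found 0% of genes changed 2-fold in either arm, 1.67% of genes changed 4-fold in the knockdown arm and 0% in the overexpression arm, and 60% and 75% of genes changed 64-fold. The list step, run on permuted ratios of the MCF7 overexpression, marked 3.9% of unshifted lists of 10 genes and 4.5% of unshifted lists of 20 genes as apart. It marked 82% and 98% of lists shifted by 0.3. Permuting breaks any link between the members of a list, so these rates do not carry over to lists of related genes. The other comparisons were not simulated, so the rates do not carry over to them either. In the MCF7 knockdown, targets of beta-catenin lay at -0.32 relative to random lists and did not stand apart.

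Small RNAs such as snoRNAs and spliceosomal RNAs, tRNA and ribosomal RNA genes, histone genes, the near-identical AKR1C genes, ribosomal protein genes with many pseudogenes, genes of the MHC region such as DDX39B and the HLA genes, and readthrough genes such as RPS10-NUDT3 share reads with copies or neighbours, and their values are uncertain. Whether the authors' counting used strand is not given in the sources used here, so antisense genes are uncertain too.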

Results

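RNA-seq profiles were analysed for MDA-MB-468, a basal-like, triple-negative breast cancer line, and MCF7, a luminal, estrogen receptor-positive breast cancer line. In each line DVL3 was knocked down with a short hairpin RNA labelled shB and compared with a non-target control (NTC), and wild-type DVL3 was overexpressed (DVL3-WT) and compared with an empty vector (EV). DVL3 is a dishevelled scaffold protein that relays Wnt signals from frizzled receptors. The series asks which genes respond to DVL3. There was 1 sample per group, 8 in all, and each value is the authors' mean RPKM of a group. Differences between groups of 1 line therefore have no replicate check beyond the authors' own p-values. Between 15796 and 19272 genes were above 0 and between 3973 and 11637 genes reached 1 RPKM per group. Read totals are unknown. The lines kept their known identities in all groups: EGFR lay between 67.7 and 321 RPKM in MDA-MB-468 and at 0.428 RPKM or less in MCF7, and the estrogen-induced gene TFF1 lay between 42.2 and 566 RPKM in MCF7 and at 0.003 RPKM or less in MDA-MB-468. Of the fixed markers of immune cells and of fibroblasts and endothelium, 1 gene each reached a mean of 1 RPKM.

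DVL3 itself, which checks the labels, was lower in the MDA-MB-468 library labelled DVL3 shB than in NTC (2.36 RPKM in NTC and 1.71 RPKM in DVL3 shB as deposited). The plain ratio, without the pseudocount, was 2.22-fold after rescaling. On log2(RPKM + 1) the ratio was -0.31 as deposited and -0.78 after rescaling, which does not pass the size rule. In the MDA-MB-468 library labelled DVL3-WT it was not higher than in EV as deposited or after rescaling: 11.5 RPKM in EV and 5.98 RPKM in DVL3-WT as deposited, a log2 ratio of -0.84, or -0.27 after rescaling, and 0.18 with scaling to the reference genes. In MCF7, DVL3 was higher in the library labelled DVL3-WT than in EV (0.874 RPKM in EV and 2.49 RPKM in DVL3-WT as deposited), with a plain ratio of 2.39-fold after rescaling. On log2(RPKM + 1) the ratio was 0.90 as deposited and 0.93 after rescaling, short of the size rule as well. After rescaling DVL3 was at 5.35 RPKM in MCF7 NTC, 1.87 in EV and 4.45 in DVL3-WT. It was thus higher in DVL3-WT than in EV but not than in NTC. DVL1 and DVL2 were also higher than in EV, with plain ratios of 1.48-fold and 1.43-fold after rescaling. In the MCF7 library labelled DVL3 shB the direction of DVL3 depended on the scaling. DVL3 was listed at 2.63 RPKM in NTC and 3.51 RPKM in DVL3 shB, a log2 ratio of 0.31, and the ratio was -1.14 after rescaling. The median of 21 widely expressed reference genes in that comparison was also -1.14 after rescaling. The authors' deposited tables list DVL3, DVL1 and DVL2 in none of the 4 comparisons. Because of these values, directions below are those of the libraries as labelled.

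**Figure D1:**
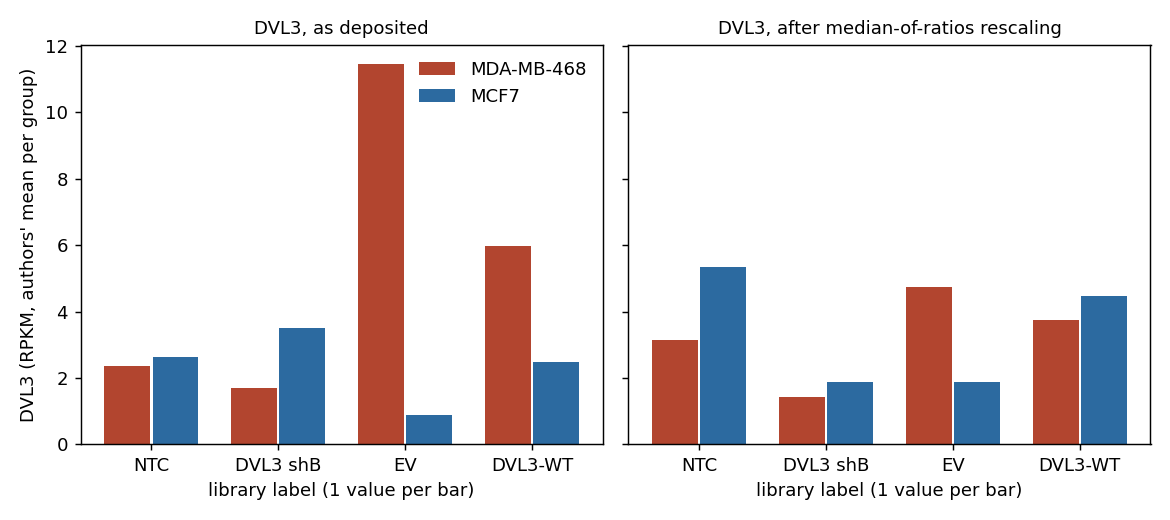
DVL3 RPKM (y axis, authors' mean per group) in the 4 library labels of MDA-MB-468 and MCF7 (x axis, 1 bar per group), as deposited on the left and after median-of-ratios rescaling on the right. In MDA-MB-468 the DVL3-WT bar lies below the EV bar in both panels (5.98 against 11.5 RPKM as deposited), and in MCF7 it lies above it (2.49 against 0.874 RPKM).

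Knockdown in MDA-MB-468 (DVL3 shB against NTC) asks which genes follow the loss of DVL3 in a basal-like line. The cell-cycle and histone lists lay above random lists in the library labelled DVL3 shB, though most of their genes were not 2-fold higher after rescaling. In counts of genes here and below, 2-fold is the size rule on RPKM + 1 and not the plain ratio. Of 24 measured cell-cycle genes, 9 were at least 2-fold higher as deposited and 3 after rescaling, and 0 were lower. UBE2C, a ubiquitin-conjugating enzyme of mitosis, was listed at 2.87 RPKM in NTC and 16.8 RPKM in DVL3 shB, and RRM2, a subunit of ribonucleotide reductase, at 3.79 and 15.9 RPKM. The list's median log2 ratio was 0.95 as deposited and 0.44 after rescaling (percentile 100; percentiles here and below are those of the deposited median among random lists). The 18 replication-dependent histone genes had a median of 1.46 as deposited and 0.79 after rescaling (percentile 100), with HIST1H4C at 12.8 and 56.0 RPKM. The EV column, without a hairpin against DVL3, was higher still against the same NTC (1.09 for cell-cycle and 1.35 for histone genes after rescaling), so these high ratios do not show an effect of losing DVL3. Genes of the unfolded protein response were also on the high side, with a median of 0.92 as deposited and 0.33 after rescaling over 22 genes (percentile 99.98). Among them the stress factor ATF3 was listed at 0.056 and 2.05 RPKM and the disulfide isomerase PDIA6 at 10.6 and 26.9 RPKM. The median of these 22 genes in EV against the same NTC was 1.87 as deposited and 0.37 after rescaling (percentile 95.05, not apart). Their high ratio in DVL3 shB therefore does not show an effect of losing DVL3 either.

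In the same comparison, 14 genes of steroid metabolism had a median of 0.85 as deposited and 0.27 after rescaling (percentile 98.92). AKR1C1 and AKR1C2, aldo-keto reductases that act on steroids, were listed at 0.307 and 4.97 RPKM and at 1.98 and 8.60 RPKM. Sterol synthesis genes (17 genes, percentile 98.63) and glycolytic enzymes (16 genes, percentile 97.98) also stood on the high side, with CYP51A1 at 2.80 and 7.91 RPKM and ENO1 at 44.7 and 120 RPKM. These 3 lists no longer stood apart after rescaling, and steroid metabolism genes were also high in EV against NTC (0.76 after rescaling). The 7 measured Wnt ligands and secreted Wnt inhibitors stood on the low side (median 0.27 as deposited and -0.25 after rescaling, percentile 1.00). Of these, WNT10A was listed at 1.90 and 1.08 RPKM and SFRP1 at 9.47 and 11.7 RPKM. This list kept its side under the 4 alternatives that could be run on it. In EV against the same NTC its median was 0.33 after rescaling (percentile 74.23, not apart). With 1 column per group an effect of the hairpin on these genes could not be tested. Luminal and estrogen response genes were mostly near 0 RPKM in this line. Their median of 0.00 (percentile 0) did not stand apart once only genes of at least 1 RPKM in the 2 columns were used, an alternative added after seeing the data. The 15 measured targets of beta-catenin did not stand apart (median 0.63 as deposited, percentile 70.88).

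Single genes with the lowest ratios were MIF, a secreted cytokine, at 14.2 RPKM in NTC and 0.818 RPKM in DVL3 shB, and the ribosomal RNAs listed as RNR1 and RNR2, at 71.3 and 10.3 RPKM and at 76.9 and 11.5 RPKM. The authors' deposited table gives RNR2 a p of 0.00699 and RNR1 a p of 0.0227, and both a second p of 1. ISG15, an interferon-induced ubiquitin-like protein, was listed at 30.8 and 16.8 RPKM, and DHRS3, a retinol-metabolizing enzyme, at 17.4 and 11.4 RPKM. Genes with the highest ratios that were near 0 in NTC included HIGD2A (0.283 and 8.81 RPKM), MRPS17 (0.214 and 8.08 RPKM) and SNRPD1 (0.139 and 6.78 RPKM). DDX39B, an RNA helicase, was listed at 0.264 and 15.7 RPKM. As deposited, 1175 genes were at least 2-fold higher and 29 lower, but the median gene was higher by 0.58 on the log2 scale. After rescaling the split was 245 higher and 49 lower. The 21 reference genes also stood on the high side (median 0.44 after rescaling, percentile 100), with ACTB at 357 and 975 RPKM, as they did in EV against NTC (0.81).

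Overexpression in MDA-MB-468 (DVL3-WT against EV) asks which genes follow added DVL3; in this pair the DVL3 transcript was not higher in the library labelled DVL3-WT as deposited or after rescaling. IGFBP5, a secreted binding protein of insulin-like growth factors, was listed at 6.03 RPKM in EV and 80.4 RPKM in DVL3-WT. The authors' deposited table gives it a fold of 13.3, a p of 0.000305 and a second p of 0.0105. SLC34A2, a sodium-phosphate cotransporter, was listed at 0.412 and 11.1 RPKM (p = 0.000134, second p = 0.00421 in the authors' deposited table), STAC2 at 2.85 and 19.98 RPKM, PALM, a membrane-associated phosphoprotein, at 0.308 and 5.66 RPKM and C2orf72 at 2.83 and 11.2 RPKM. GSTP1, a glutathione transferase, went from 48.6 RPKM in EV to 0.002 RPKM in DVL3-WT. AKR1B1, aldose reductase, was listed at 131 and 10.4 RPKM, with a fold of 0.0794, p = 0.0002 and a second p of 0.00828 in the authors' deposited table, where GSTP1 has p = 0.00598 and a second p of 0.0988. ID1, an inhibitor of DNA binding induced by BMP signals, was listed at 58.2 and 6.12 RPKM (p = 0.000385, second p = 0.0155 in the authors' deposited table), and the nuclear RNA MALAT1 at 187 and 19.25 RPKM.

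**Figure D2:**
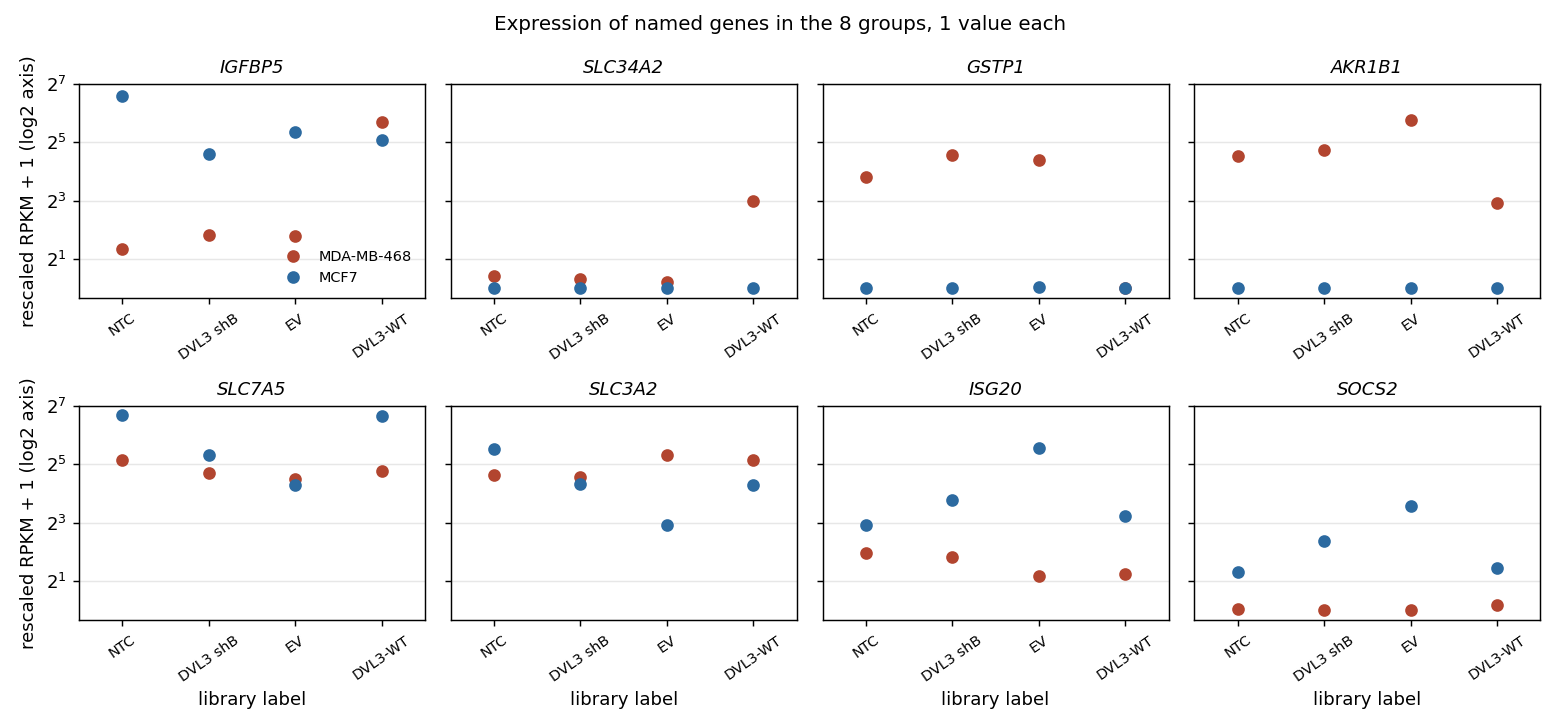
Rescaled RPKM plus 1 (y axis, log2 scale) of 8 named genes in the 4 library labels (x axis), with 1 point per group for MDA-MB-468 and MCF7. IGFBP5 and SLC34A2 are high and GSTP1 and AKR1B1 low in the MDA-MB-468 library labelled DVL3-WT (rescaled log2 ratios of 3.88, 2.76, -4.39 and -2.87 against EV), and SLC7A5 and SLC3A2 are higher and ISG20 and SOCS2 lower in the MCF7 library labelled DVL3-WT than in EV (2.36, 1.38, -2.34 and -2.10). In MCF7, ISG20 and SOCS2 lie near their NTC level in DVL3-WT and higher in EV.

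By list, mitochondrially encoded genes lay farthest from random lists: 13 of 13 were at least 2-fold lower as deposited and 11 of 13 after rescaling, with a median of -2.16 as deposited and -1.53 after rescaling (percentile 0). COX1 was listed at 129 and 19.5 RPKM and ND1 at 70.7 and 11.2 RPKM. Ribosomal protein genes had a median of -0.85 after rescaling (12 of 32 at least 2-fold lower, percentile 0), histone genes -0.94 (8 of 18, percentile 0), heat-shock chaperones -0.66 (4 of 14, percentile 0.04) and cell-cycle genes -0.51 (6 of 24, percentile 0.01). Examples were RPS27 at 46.2 and 5.97 RPKM, HIST2H2BE at 34.1 and 5.64 RPKM, HSPB1 at 214 and 49.5 RPKM, PCNA at 23.1 and 4.52 RPKM and MKI67 at 7.24 and 1.40 RPKM. Steroid metabolism genes also stood on the low side (median -0.51 after rescaling, percentile 0.82), with AKR1C2 at 92.6 and 18.3 RPKM and AKR1C3 at 5.80 and 0.731 RPKM. The EV column itself stood high in these 6 lists against NTC (medians after rescaling of 1.04, 1.02, 1.35, 0.78, 1.09 and 0.76 in the order given), so these low ratios do not show a lowering by DVL3-WT. Glycolytic enzymes had a median of -0.33 after rescaling (percentile 2.37, not apart after rescaling), with LDHA at 35.2 and 9.37 RPKM.

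Sterol synthesis and uptake genes stood on the high side relative to other genes, at -0.26 as deposited and 0.25 after rescaling (17 genes, percentile 99.99). INSIG1, a sterol sensor partner, was listed at 6.62 and 10.98 RPKM, and the LDL receptor LDLR at 13.6 and 21.5 RPKM. The list kept its side under 5 of 5 alternatives. In EV against NTC its median was -0.14 after rescaling (percentile 7.55, not apart). With 1 column per group an effect of DVL3-WT on these genes could not be tested. Basal identity genes (14 genes, median 0.13 after rescaling, percentile 99.90) went both ways, with S100A2 at 19.8 and 45.3 RPKM and KRT5, named here after its value was seen, at 263 and 52.9 RPKM. Antigen presentation genes had a median of 0.17 after rescaling (13 genes, percentile 99.46), with HLA-B at 39.9 and 45.0 RPKM, and did not stand apart with members of at least 5 RPKM (percentile 94.83). They were low in EV against NTC (-0.58 after rescaling), so this high ratio does not show a raising by DVL3-WT. Luminal genes, mostly near 0 RPKM in this line, had a median of -0.08 as deposited and did not stand apart after rescaling. Targets of beta-catenin did not stand apart (median -0.22 after rescaling, percentile 39.04). As deposited, 41 genes were at least 2-fold higher and 3303 lower, and the median gene was lower, at -0.73 on the log2 scale. After rescaling the split was 85 higher and 415 lower, and reference genes had a median of -0.39 (percentile 0.16).

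Knockdown in MCF7 (DVL3 shB against NTC) showed ribosomal protein genes low in the library labelled DVL3 shB, relative to other genes, under all alternatives. Luminal and estrogen response genes were high as deposited, which held under 1 of 5 alternatives. TFF1 was listed at 42.2 RPKM in NTC and 566 RPKM in DVL3 shB, TFF3 at 2.33 and 34.7 RPKM, the secretory factor XBP1 at 39.2 and 411 RPKM and the receptor kinase RET at 1.36 and 18.3 RPKM. The authors' deposited table gives RET a p of 0.0399 and a second p of 0.764. The 15 luminal genes had a median of 1.86 as deposited (14 at least 2-fold higher, percentile 98.72) and 0.22 after rescaling (4 at least 2-fold higher and 1 lower), where they did not stand apart, nor did they with a pseudocount of 0.1, members of at least 5 RPKM or matching by the 2 columns. Of 32 ribosomal protein genes, 31 were at least 2-fold lower after rescaling and 6 as deposited (median -2.13 and -0.32, percentile 0). RPS18 was listed at 31.3 and 9.78 RPKM and RPS24 at 52.3 and 19.45 RPKM.

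Other lists on the low side were heat-shock chaperones (median 0.01 as deposited and -1.66 after rescaling, percentile 0), with HSP90AA1 at 42.8 and 32.8 RPKM, mitochondrially encoded genes (0.69 and -1.11, percentile 0.80), with COX3 at 12.8 and 11.9 RPKM, histone genes (0.82 and -0.89, percentile 1.74) and cell-cycle genes (0.54 and -0.73, percentile 0.78), with CDK1 at 0.573 and 0.057 RPKM. Cell-cycle genes did not stand apart when only members of at least 5 RPKM were used (percentile 12.595) or when matching used the 2 columns (6.57). Epithelial junction and identity genes did not stand apart as deposited (percentile 3.175) but stood low under 3 of 5 alternatives, with 8 of 19 at least 2-fold lower after rescaling. In EV against the same NTC, ribosomal protein, heat-shock, histone, cell-cycle and epithelial genes were lower still (-2.71, -2.19, -2.27, -1.34 and -1.38 after rescaling), so these low ratios do not show an effect of the hairpin. Mitochondrially encoded genes were not low in EV against NTC (0.01 after rescaling, percentile 59.66). With 1 column per group an effect of the hairpin on them could not be tested. YAP and TAZ targets (percentile 0.38), basal identity genes (percentile 0) and NF-kB targets (percentile 0.37) also stood on the low side as deposited, but not after rescaling; many of their members were near 0 RPKM in this line. In these lists CRIM1 was listed at 4.15 and 4.34 RPKM, KRT17 at 1.52 and 0.535 RPKM and SOD2 at 1.35 and 0.898 RPKM. Targets of beta-catenin had a median of -0.27 after rescaling (percentile 9.24 as deposited).

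Among single genes, ID1 was listed at 1.51 and 50.6 RPKM, the adaptor SCIMP at 0.28 and 29.2 RPKM and the channel subunit LRRC26 at 0.205 and 19.1 RPKM. The other highest ratios included FAM122C (21.7 and 399 RPKM) and the antisense genes FRY-AS1 (4.002 and 83.6 RPKM) and ZNRF3-AS1 (7.94 and 146 RPKM). GSG1L, a subunit of AMPA receptors, was lower, at 6.06 and 0.659 RPKM (p = 0.00971, second p = 0.764 in the authors' deposited table), and S100A10 was listed at 7.89 and 2.65 RPKM. DVL1 was higher as deposited, with a log2 ratio of 1.33, and at -0.33 after rescaling. As deposited, 4156 genes were at least 2-fold higher and 63 lower, with the median gene at 0.89, and after rescaling 1120 were higher and 1515 lower. Reference genes had a median of -1.14 after rescaling (percentile 0.01), so directions in this comparison depend on the scaling.

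Overexpression in MCF7 (DVL3-WT against EV) was the comparison with the smallest shift of all genes (median 0.03 on the log2 scale). SLC7A5 and SLC3A2, the light and heavy chain of a transporter of large amino acids, were both higher in the library labelled DVL3-WT, at 8.76 and 55.9 RPKM and at 3.07 and 10.5 RPKM. The authors' deposited table gives SLC7A5 a fold of 6.38 (log2 fold 2.67) with p = 0.000307 and a second p of 0.336, and SLC3A2 a fold of 3.41 with p = 0.0293 and a second p of 1. WISP2, a secreted protein of the CCN family, was listed at 2.89 and 15.4 RPKM, the calcium-binding protein EFHD1 at 1.01 and 6.10 RPKM and RRS1, a ribosome assembly factor, at 1.53 and 7.03 RPKM. SOCS2, a suppressor of cytokine signalling, was lower, at 5.07 and 0.986 RPKM (p = 0.00171, second p = 0.805 in the authors' deposited table), as were the exonuclease ISG20 at 21.6 and 4.63 RPKM (p = 0.0345, second p = 1) and the calmodulin-like gene CALML5 at 7.85 and 1.95 RPKM (p = 0.0158, second p = 1). The NTC column puts a limit on these low ratios. After rescaling, SOCS2 was at 1.47 RPKM in NTC, 10.8 in EV and 1.76 in DVL3-WT, and ISG20 at 6.61, 46.1 and 8.28. In DVL3-WT both were thus near their NTC level, so their ratios to EV do not show a lowering by DVL3-WT. CALML5 was at 7.55, 16.7 and 3.49 RPKM in the same order. The sulfotransferase HS3ST3A1 was listed at 9.22 and 3.42 RPKM and the splicing regulator RBM4 at 5.21 and 0.752 RPKM.

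On the high side stood 3 lists, and 0 on the low side. Cell-cycle genes were below the bound as deposited (median 0.13, percentile 88.42) but stood on the high side under all 5 alternatives (median 0.13 and percentile 98.23 after rescaling), and heat-shock chaperones (percentile 97.05) under 4 of 5. Hypoxia genes had a median of 0.29 as deposited and 0.24 after rescaling (11 genes, percentile 98.78), with the angiogenic factor VEGFA at 5.07 and 11.8 RPKM with p = 0.00915 and a second p of 1 in the authors' deposited table. Glycolytic enzymes had a median of 0.29 as deposited and 0.18 after rescaling (16 genes, percentile 97.84), with TPI1 at 6.37 and 13.9 RPKM and PKM at 13.8 and 25.1 RPKM. Histone genes had a median of 0.35 as deposited and 0.19 after rescaling (18 genes, percentile 98.48), with HIST1H1B at 20.2 and 44.0 RPKM. The EV column itself was low against NTC in histone, glycolytic, heat-shock and cell-cycle genes (-2.27, -1.99, -2.19 and -1.34 after rescaling), so these high ratios do not show a raising by DVL3-WT. The median of the hypoxia genes in EV against NTC was -1.03 after rescaling (percentile 21.24, not apart). Their high ratio therefore does not show a raising by DVL3-WT either. Hypoxia genes did not stand apart with a pseudocount of 0.1 (percentile 97.325), nor glycolytic enzymes with members of at least 5 RPKM (percentile 93.175). Luminal genes (median 0.03, percentile 53.34) and targets of beta-catenin (median 0.00, percentile 35.42) did not stand apart. As deposited, 95 genes were at least 2-fold higher and 39 lower. After rescaling 126 were higher and 159 lower, and reference genes did not stand apart.

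**Figure D3:**
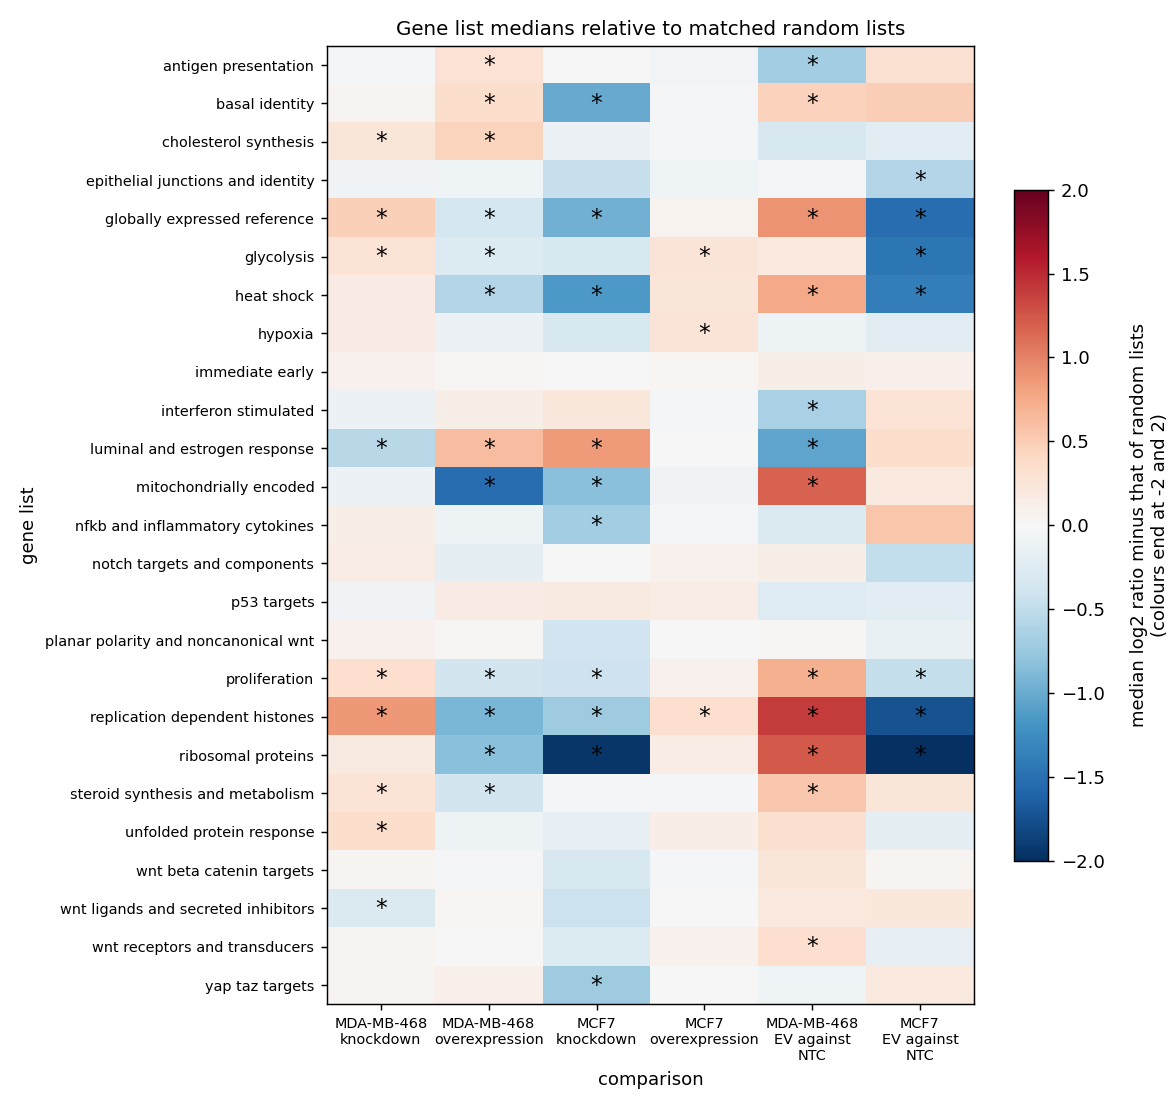
Median log2 ratio of each gene list minus that of matched random lists (colour), for 25 lists (y axis) in the 4 comparisons and in EV against NTC of each line (x axis), as deposited. A star marks a list that stands apart. Histone and reference genes are high in the MDA-MB-468 and low in the MCF7 control comparison (histone genes 1.40 and -1.74), and targets of beta-catenin carry no star in any column.

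The control columns of 1 line, EV and NTC, were compared as well, and in MCF7 how far they lay apart relative to the knockdown depended on the scaling (3752 and 4219 genes as deposited). After rescaling, 1257 genes in MDA-MB-468 and 5382 genes in MCF7 were at least 2-fold apart between EV and NTC, against 294 and 500 genes in the MDA-MB-468 and 2635 and 285 genes in the MCF7 comparisons of DVL3. As deposited, 9294 genes were higher and 24 lower in EV in MDA-MB-468 (median gene 1.61), and 1505 higher and 2247 lower in MCF7 (median gene -0.50). After rescaling the splits were 1127 higher and 130 lower, and 1781 higher and 3601 lower. In MDA-MB-468 the EV column was high in histone genes (median 1.35 after rescaling), cell-cycle genes (1.09), mitochondrially encoded genes (1.04) and ribosomal protein genes (1.02), and low in antigen presentation genes (-0.58). In MCF7 the EV column was low in ribosomal protein genes (-2.71), histone genes (-2.27), heat-shock chaperones (-2.19), glycolytic enzymes (-1.99) and cell-cycle genes (-1.34). Of the 25 lists, 9 stood high and 3 low in the control comparison of MDA-MB-468, and 0 and 7 in that of MCF7. For MDA-MB-468 these counts were 7 and 2 in the knockdown and 4 and 8 in the overexpression. For MCF7 they were 1 and 9 in the knockdown and 3 and 0 in the overexpression. Standing apart was therefore not particular to the DVL3 comparisons. Some lists that stood apart in a DVL3 comparison, such as Wnt ligands and sterol synthesis in MDA-MB-468, did not in the control comparison of the line.

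An effect of DVL3 common to both lines was tested with limma, with the lines as replicates. At an adjusted p of 0.05, 0 of 8683 genes passed for the knockdown and 0 for the overexpression; at an unadjusted p under 0.05 there were 18 and 6 genes, where chance gives 434, and 1301 and 83 when only the 4 columns of an arm were fitted, with 0 genes at the adjusted p. Genes with the largest shared ratios in the knockdown were the mucin MUC1, at 20.2 and 76.6 RPKM in MDA-MB-468 and 2.24 and 48.8 RPKM in MCF7 (fitted log2 fold 2.91, SE 1.26, adjusted p = 0.77 by limma), PHKG1 at 1.52 and 7.73 RPKM and at 0.09 and 5.31 RPKM, DPM3, HIST1H2AI and the tight-junction gene CLDN4. CLDN4, HIST1H2AI and DPM3 were not higher by 2-fold in MCF7 after rescaling (log2 ratios of -0.03, 0.02 and 0.48). The lowest were 5 copies of 5S ribosomal RNA with identical values (RNA5S1 to RNA5S5). In the overexpression the shared genes were CEBPD, a transcription factor, at 26.2 and 53.4 RPKM and at 2.91 and 9.29 RPKM (fitted log2 fold 1.20, SE 1.23, adjusted p = 1 by limma), EFHD1, TNNT1, RIMS4 and SNORA74B on the high side and RBM4, SERP1, TMEM64, CD59 and SNORD10 on the low side. Leaving out a column of the compared arms leaves that arm with 1 line, so those fits cannot test an effect common to both lines. Without the MDA-MB-468 NTC column the median fitted log2 fold of the knockdown was 0.17, against 0.79 with all 8 columns. Without the MCF7 EV column that of the overexpression was -1.18, against -0.36 with all 8 columns. On simulated data with the real residual spread the fit of all 8 columns found 60% of genes changed 64-fold in the knockdown and 75% in the overexpression. Changes of 2-fold shared by both lines were below what it could find. The simulation used the spread of values as deposited, which column-wide shifts enter, and drew noise for each gene alone. The fit after rescaling was not simulated.

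Genes that moved in opposite directions with knockdown and overexpression of 1 line were counted, since the pairs share no control. Chance counts are those of independent lists among genes that could pass the size rule in both comparisons, with at least 1 RPKM in the higher column of each. In MCF7, 26 genes were at least 2-fold higher in DVL3 shB and lower in DVL3-WT as deposited, where chance gives 27.4, and 2 genes were lower and then higher, where it gives 0.264. At the same time 54 genes were higher in both, where chance gives 67.3. The opposite genes included ISG20 (3.25 and 23.96 RPKM in the knockdown pair), SOCS2 (0.724 and 7.76 RPKM), CALML5 (3.71 and 26.2 RPKM) and S100A6, which were higher and then lower. GSG1L (2.07 RPKM in EV and 6.87 RPKM in DVL3-WT) was lower and then higher. ISG20, CALML5 and S100A6 fell short of the size rule in the knockdown after rescaling (log2 ratios of 0.87, 0.82 and 0.34). SOCS2 (1.06 and -2.10) and GSG1L (-3.30 and 1.295) still passed it in both pairs. After rescaling the counts were 20 and 40, where chance gives 25.9 and 17.4, while 37 genes were lower in both and 3 higher in both, where it gives 19.9 and 22.6. In MDA-MB-468, 625 genes were higher in DVL3 shB and lower in DVL3-WT and 1 was the reverse, where chance gives 328 and 0.0429, while 5 were higher in both and 4 lower in both, where it gives 4.18 and 3.37. After rescaling the opposite counts were 53 and 4, where chance gives 10.5 and 0.255, and the counts in the same direction were 5 and 6, where it gives 2.13 and 1.26. The controls NTC and EV of this line were at least 2-fold apart in 1257 genes after rescaling, and DVL3 shB and DVL3-WT in 216. The controls of MCF7 were at least 2-fold apart in 5382 genes after rescaling. In either line a gene that differs between the controls can count as opposite, so an excess over chance does not show an effect of DVL3. The 625 genes included OST4, a subunit of oligosaccharyltransferase, at 0.237 and 6.56 RPKM in the knockdown pair and 19.6 and 3.21 RPKM in the overexpression pair, C15orf38, FAM27B and the small RNAs TRNAL7 and SNORA80. Across 8683 genes the log2 ratios of knockdown and overexpression had a Pearson correlation of -0.28 in MDA-MB-468 and -0.21 in MCF7 (Spearman -0.33 and -0.17). Between the lines it was -0.23 for the knockdown and 0.07 for the overexpression (Spearman -0.30 and 0.03). The MCF7 knockdown also had a correlation of -0.46 (-0.55 after rescaling) with EV against NTC of MDA-MB-468, a control comparison without a hairpin against DVL3, so a correlation of this size was not particular to DVL3. Genes are not independent replicates.

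The authors' deposited tables list 224 genes for the MDA-MB-468 knockdown (183 higher and 41 lower), 4964 for the MDA-MB-468 overexpression (122 higher and 4842 lower), 570 for the MCF7 knockdown (529 higher and 41 lower) and 410 for the MCF7 overexpression (200 higher and 210 lower). The listed folds are ratios of RPKM as deposited, so a shift of all genes of a column enters these splits. Of the listed genes, 222, 4950, 568 and 409 were among the 27628 used here. As deposited, 48, 2388, 127 and 44 of them passed the size rule. After rescaling, 27, 393, 25 and 88 passed it in the listed direction. In the MCF7 knockdown 535 of 568 kept their direction after rescaling, and in the other comparisons all did. At the second p under 0.05 the authors' deposited tables hold 0, 378, 97 and 143 genes. The genes listed by the authors' deposited tables for both knockdowns were 12, of which 9 had the same direction and 3 the opposite one, where independent lists among 27628 genes give 3.51 and 1.05. The 9 included AKR1C3, MYCN, INHBA and HOXC9, named here after their values were seen. In both overexpressions 133 genes were listed, 87 in the same direction and 46 in the opposite one (37.4 and 35.9). Within MDA-MB-468 the knockdown and the overexpression shared 33 genes, 9 in the same direction and 24 in the opposite one (7.96 and 31.8), and within MCF7 30 genes, 11 and 19 (4.13 and 4.28). The MDA-MB-468 overexpression and the MCF7 knockdown shared 173 genes, 13 and 160 (9.49 and 92.3). Many of the 27628 genes are too low to be listed, so these chance counts are too small. In 47, 2401, 30 and 60 of the listed genes both groups reached 1 RPKM.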

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

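The tests of genomic DNA and of transcript length were written before their results were seen; the tests of a loss of DVL3 as the whole cause, of the scaling of the columns, of an exchange of EV and DVL3-WT, and of a floor for values of 0 were chosen after the results were seen.

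Some gene lists lay on opposite sides of their random lists in the lines, which is a difference between groups; the difference was not tested. In the knockdown, the median log2 ratio minus that of random lists was 0.87 in MDA-MB-468 and -0.72 in MCF7 for histone genes, 0.47 and -0.96 for reference genes, 0.34 and -0.42 for cell-cycle genes, and -0.56 and 0.85 for luminal and estrogen response genes, whose members were mostly near 0 RPKM in MDA-MB-468. In the overexpression it was -0.92 and 0.34 for histone genes and -0.27 and 0.26 for glycolytic enzymes.

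In MCF7 the EV column was low in ribosomal protein, histone and reference genes against NTC. Transcript length was argued against as the whole cause: the ribosomal protein genes lay at -1.65 on the log2 scale relative to random genes of like length (percentile 0). Histone genes lay at -0.88 (percentile 0.64) and reference genes at -1.27 (percentile 0) in the same check. The random genes of like length were themselves at -1.07, -1.39 and -0.90 for these 3 lists, so a part that goes with length stays open. Genomic DNA reads in the EV libraries stay open, since the value they need was there: 13.6% of 374 olfactory receptor genes were above 0 in EV and 3.74% in NTC, a ratio of 3.64. Against this stand the level and the depth: the highest such value in EV was 0.009 RPKM, and a larger number of reads could raise the share as well. In the MDA-MB-468 EV column, where ribosomal protein genes were high, the share was also larger than in NTC (8.29% and 2.41%). The vector, the day of culture and the preparation of the libraries were not tested and stay open. Ribosomal protein genes were low in the MCF7 column labelled DVL3 shB too. A loss of DVL3 as the whole cause cannot be told apart from other causes: the EV column, which holds no hairpin against DVL3, lay at -2.71 (quartiles -2.98 and -2.42) for these genes, but it was set against the same NTC and its DVL3 was lower too, with a log2 ratio of -1.15 after rescaling.

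DVL3 was not higher in the MDA-MB-468 library labelled DVL3-WT than in EV. The scaling of the columns decided the sign, with log2 ratios from -0.84 as deposited to 0.18 with scaling to the reference genes, but under none of the scalings run did DVL3 reach the 0.58 set as the bound. An exchange of the EV and DVL3-WT labels cannot be told apart from other causes, since DVL3 in EV was 1.26 times that in DVL3-WT after rescaling, with 1 column per group. An expression construct whose transcript is not counted as DVL3 was not tested, and no biological explanation was tested.

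The genes that the authors' deposited tables list at a second p under 0.05 were mostly genes with 1 group at 0 RPKM. Such genes made up 80.6% in the MDA-MB-468 overexpression and 100% in the MCF7 knockdown and in the MCF7 overexpression, against 0.109%, 18.5% and 6.02% of the other listed genes. A fixed floor in place of 0 before the authors' test and genes that are switched off cannot be told apart here, since these shares are the pattern itself.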

How the results depend on the processing

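Quantile normalization and scaling to the reference genes for DVL3, matching of lists by the 2 columns compared, rescaling of the correlations, and both alternatives for named genes were added after the data had been seen; all other alternatives were fixed before.

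The number of genes past the size rule moved with nearly every setting, and the cause was not tested. In the order MDA-MB-468 knockdown, MDA-MB-468 overexpression, MCF7 knockdown, MCF7 overexpression, the totals were 1204, 3344, 4219 and 134 as deposited, 5068, 8188, 7928 and 1788 with a pseudocount of 0.1, 2218, 5136, 5396 and 321 with a pseudocount of 0.5, 771, 2146, 2916 and 76 with genes of at least 5 RPKM only, 294, 500, 2635 and 285 after rescaling, and 256, 428, 2632 and 448 after quantile normalization. The minimum of 5 RPKM lowers a total by its construction. For EV against NTC the totals in MDA-MB-468 and MCF7 were 9318 and 3752 as deposited, 13991 and 9162 with a pseudocount of 0.1, 5802 and 1960 with genes of at least 5 RPKM, 1257 and 5382 after rescaling, and 935 and 4663 after quantile normalization. DVL3 kept its sign in 3 of the 4 comparisons under rescaling. In the MCF7 knockdown its log2 ratio went from 0.31 to -1.14 under rescaling, and was -0.94 after quantile normalization and -0.07 with scaling to the reference genes. In the MDA-MB-468 overexpression it was 0.18 with scaling to the reference genes, against -0.84 as deposited. In the MDA-MB-468 knockdown it was -1.22 with scaling to the reference genes, and in the MCF7 overexpression it was 1.41 with a pseudocount of 0.1 and 1.13 with scaling to the reference genes. No list that stood apart turned to the opposite side under any setting. The number of lists standing apart was 9 in the MDA-MB-468 knockdown and 5 of these stayed after rescaling; in the MCF7 knockdown it was 10, and 6 when members and matching used the 2 columns compared, 5 of them among the 10; and the 3 in the MCF7 overexpression became 5 after rescaling, 6 with the mean of the members and 7 with matching by the 2 columns, while hypoxia genes were lost with a pseudocount of 0.1 and glycolytic enzymes with members of at least 5 RPKM. In the MDA-MB-468 overexpression, antigen presentation genes were lost with members of at least 5 RPKM and basal identity genes with the mean of the members. Reciprocal genes in MDA-MB-468 were 626 as deposited, 3148 with a pseudocount of 0.1, 57 after rescaling and 398 with genes of at least 5 RPKM; in MCF7 they were 28, 282, 60 and 21. The correlation of knockdown and overexpression in MCF7 was -0.21 as deposited, -0.44 with genes of at least 10 RPKM, -0.11 after quantile normalization and -0.33 after rescaling. The correlation of the knockdowns of both lines was -0.23, -0.47, -0.33 and -0.35 in the same order, and the other Pearson correlations moved by less than 0.1. Between the overexpressions of both lines it was 0.07 as deposited and 0.02 after rescaling (Spearman 0.03 and -0.03). The authors' deposited tables held 65, 1195, 221 and 200 genes at a p under 0.01. Of 223 log2 ratios of named genes, 162 kept their side of the size rule after rescaling and 61 did not. Among ratios of at least 1 in size, 1 changed sign, which was DVL1 in the MCF7 knockdown (1.33 as deposited and -0.33 after rescaling); the genes named for the common effect are not among the 223, and of these CLDN4 went from 1.77 to -0.03 in the MCF7 knockdown; among all 223, 20 changed sign. With a pseudocount of 0.1, 218 kept their side of the size rule and 5 did not. The effect common to both lines had 0 genes at an adjusted p of 0.05 by limma in the knockdown and in the overexpression, against 18 and 6 genes at an unadjusted p under 0.05, and 0 under all settings other than leaving out a column. The unadjusted counts moved: they were 1301 and 83 with only the 4 columns of an arm, 795 for the knockdown without MDA-MB-468 NTC and 687 for the overexpression without MCF7 EV. Leaving out 1 column at a time gave 0 to 117 genes in the knockdown, with 117 without MDA-MB-468 NTC, and 0 to 2 in the overexpression, with 2 without MCF7 EV. The limma fit compared the arms within each cell line through its term for line. No pairing within a line was possible because each group had 1 column per line. Read totals are unknown, so what depth limits could not be measured.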

Other observations

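In MDA-MB-468, IGFBP5 and GSTP1 set the library labelled DVL3-WT apart from the other 3. After rescaling, in the order NTC, DVL3 shB, EV and DVL3-WT, IGFBP5 was at 1.54, 2.51, 2.49 and 50.5 RPKM and GSTP1 at 12.9, 22.9, 20.1 and 0.00126 RPKM.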
